A study of Mus musculus with 24 samples.

How the data were processed

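RNA was sequenced from pools of mouse preimplantation embryos and from MII oocytes, in 24 libraries that fall into 12 groups of 2. Per the labels, PR-DUB libraries (control, CTR, and overexpression, OE) and KDM6B libraries (CTR and OE) were made at the 2-cell and the 4-cell stage, Eed libraries (CTR and maternal knockout, matKO) at the 4-cell stage, and untreated libraries from MII oocytes and late 2-cell embryos. PR-DUB is a complex of BAP1 and an ASXL protein that removes ubiquitin from histone H2A (H2AK119ub); KDM6B removes methyl groups from lysine 27 of histone H3; EED is a core subunit of PRC2, which writes that methylation. Most embryos came from B6/DBA females crossed with PWK males, those of the Eed experiment from females of a mixed B6/129 background crossed with PWK males. The late 2-cell embryos came from B6/DBA parents. The labels do not say what the control pools received, nor whether the 2 libraries of a group came from separate collections, so every p-value measures the spread between these libraries. A PR-DUB 2-cell library held 15 embryos, a PR-DUB 4-cell library 19 (CTR) or 16 (OE), and a KDM6B 2-cell library 17 or 18; the other numbers are not given in the sources used here.

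Groups were taken from the sample titles. For the 2 KDM6B OE 2-cell libraries the manipulation field names PR-DUB instead (written PR-DUP), and for the 2 Eed knockout libraries the title says OE where the manipulation field says matKO; the title was followed in the first case and the manipulation field in the second. The late 2-cell libraries are the columns headed 30hpf.

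The deposited values are FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library) made by the authors with Trim Galore 0.6.5, HISAT2 2.1.0 and StringTie 1.3.3b on mm10, per the submitters' processing notes. A low-input stranded SMART-Seq kit was used. The first 12 samples were sequenced on a NextSeq550, the other 12 (KDM6B 4-cell, Eed, MII and late 2-cell) on a NextSeq550 or a HiSeq2000. The comparison of KDM6B 4-cell with KDM6B 2-cell libraries crosses that split, and treated and control libraries of one stage do not. The instrument of each of the other 12 is not stated here, so a difference of instrument within their comparisons is not excluded. The values come as 3 tables. The first holds the 16 PR-DUB and KDM6B libraries and the second the 4 Eed libraries, each with 46078 genes. The third holds the MII and late 2-cell libraries with 55573 genes and so rests on another annotation release. The release is not given in the sources used here. Of the gene identifiers, 45143, 45143 and 55394 were found in GENCODE vM21, which supplied symbols, positions on mm10 and biotypes. In each of them 27 gene names had turned into dates and were restored from their identifiers. No column was left out, and each table was analysed on its own.

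Read counts were not used here. If the smallest step of FPKM times gene length in a library is 1 fragment, the libraries hold 11.6 to 20.6 M mapped fragments, and a gene of 2 kb at 1 FPKM rests on 23.1 to 41.2 fragments. PCR copies are not independent molecules, so these numbers bound counting error only.

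FPKM were transformed to log2(FPKM + 1), so that a fold change of a low gene is understated on this scale; ratios of mean FPKM are given beside it. Genes with an FPKM of at least 1 in at least 2 libraries of a table were tested: 15055, 11679 and 13237. The test was limma's moderated test (limma 3.58.1 in R 4.3.3, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The first table was fitted as 8 group means, which share 1 estimate of spread per gene (8 residual degrees of freedom); the other tables have 2 residual degrees of freedom each. A plain exact permutation test of 2 libraries against 2 cannot go below p = 0.333. The comparisons were OE against CTR at each stage, Eed matKO against CTR, late 2-cell against MII oocyte, PR-DUB CTR 4-cell against PR-DUB CTR 2-cell, and 4 differences between effects (PR-DUB 4-cell minus 2-cell, KDM6B 4-cell minus 2-cell, and PR-DUB minus KDM6B at each stage). Errors of fold changes are standard errors (SE) of that fit; errors of FPKM are standard deviations (SD).

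Gene lists were tested with camera of limma, which compares a list's genes with all other genes, with the preset correlation of 0.01 and adjustment over the lists tested in a comparison; lists with at least 5 tested genes were tested. As a second check fry of limma asked whether a list moves in 1 direction, without comparing it with other genes. The lists are subunits of PR-DUB and PRC1; subunits of PRC2 with H3K27 demethylases; developmental regulators; H3K27me3-imprinted genes; canonical imprinted genes; 2-cell-stage transient genes; maternal oocyte transcripts; ribosomal proteins; ribosome biogenesis; the proteasome; the spliceosome; pluripotency, trophectoderm and primitive endoderm genes; p53 targets; the integrated stress and unfolded protein response; heat shock genes; mitochondrially encoded genes; glycolysis; markers of cumulus and granulosa cells, sperm and blood cells; X-linked and Y-linked genes; and the genes at least 4-fold higher or lower in late 2-cell embryos than in MII oocytes at an adjusted p under 0.05. Overlaps of calls were tested with Fisher's exact test across genes. Comparisons of the same fit share 1 estimate of spread per gene, so their lists are not independent and these p-values are descriptive. Each effect was also correlated across genes with the 4-cell minus 2-cell difference of the other experiment's controls.

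Genes were named by rule: the targeted genes; the 10 called genes with the largest rise and the 10 with the largest fall, with a mean of at least 5 FPKM in the higher group and no overlap between libraries, leaving out predicted genes named Gm or Rik; up to 4 called genes with the lowest adjusted p from each list; and Xist with 5 H3K27me3-imprinted genes (Gab1, Sfmbt2, Slc38a4, Jade1, Smoc1). Not every gene picked by the rule is reported here. Tests, lists, the naming rule and the alternatives were fixed before the data were examined. The alternatives were a pseudocount of 0.1, no filter, rescaling of the libraries by median ratios to a reference, a fold of at least 2, a fit on a comparison's own libraries, a block for the replicate number, leaving out each library, and an inter-gene correlation estimated per list. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for reading and drawing.

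The test was run on simulated data of the same size with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those of at least 5 FPKM in the first group of each fit, and noise was independent between genes. Recovery of lower genes and the effect of correlation between genes were therefore not covered. With variances taken from the moderated estimates, 56% and 96% were recovered with the PR-DUB 2-cell layout (7 false calls), 79% and 100% with the Eed layout (24 false calls), and 85% and 100% with the late 2-cell layout (13 false calls). A second version, with variances drawn from the fitted prior, was added after the first result was seen. It recovered 39% and 95% (12 false calls), 41% and 91% (6 false calls), and 39% and 92% (16 false calls). With no gene changed, both versions made 0 limma calls in the KDM6B 4-cell layout.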

Results

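Transcript levels were measured by RNA sequencing in 24 libraries, 12 groups of n = 2, from mouse embryos at the 2-cell and 4-cell stages and from MII oocytes. PR-DUB OE and CTR and KDM6B OE and CTR were each represented at both stages, Eed matKO and CTR at the 4-cell stage, and untreated material by MII oocytes and late 2-cell embryos. Between 10855 and 11801 genes per library reached an FPKM of at least 1. The 2 libraries of a group correlated with each other across genes at r = 0.96 to 0.988 on the log2(FPKM + 1) scale, with genes not being independent replicates. The nuclear RNA Gm23935 held 0.85% to 28.65% of a library's total FPKM, and the 7SL and 7SK RNAs held 0.59% to 20.12%. PR-DUB OE libraries listed more genes at 1 FPKM or above than their controls, with 11772 and 11553 against 10966 and 11025 at the 2-cell stage and 11801 and 11594 against 10855 and 11087 at the 4-cell stage. Below, values after ± are SD over n = 2 libraries unless given as SE, adjusted p-values are from limma, and log2 changes are on the log2(FPKM + 1) scale.

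The transcripts that the manipulations target were measured first. Kdm6b (chromosome 11, 69398508 to 69413675), which encodes the H3K27 demethylase, stood at 14600 and 14700 FPKM in KDM6B CTR and at 14200 and 9810 FPKM in KDM6B OE 2-cell libraries, against 21.1 to 26.4 FPKM in the PR-DUB libraries of that stage. At the 4-cell stage it stood at 571 and 401 FPKM in KDM6B CTR, 597 and 547 FPKM in KDM6B OE, and 5.24 to 7.36 FPKM in the PR-DUB libraries. OE and CTR did not differ for Kdm6b by limma at the 2-cell stage (log2 change -0.31, SE 0.18, adjusted p = 0.481) or at the 4-cell stage (0.26, SE 0.18, adjusted p = 0.636). High Kdm6b therefore marked all 8 libraries of the KDM6B experiment, the 2 whose manipulation field names PR-DUB included, and gene-level FPKM did not separate OE from CTR. Bap1 (chromosome 14, 31251450 to 31259944), the catalytic subunit of PR-DUB, stood at 17.2 ± 1.57 FPKM in PR-DUB CTR and 21.1 ± 1.25 in OE at the 2-cell stage (adjusted p = 0.55). At the 4-cell stage Bap1 stood at 6.11 ± 0.124 and 9.73 ± 1.3 FPKM (log2 change 0.59, SE 0.19, adjusted p = 0.0504, not called). Its partner Asxl2 fell at the 4-cell stage from 38.7 ± 2.48 to 22.7 ± 2.67 FPKM (adjusted p = 0.0185), while Asxl1 stood at 12.5 ± 0.437 and 9.22 ± 2.3 FPKM (adjusted p = 0.117). Eed (chromosome 7, 89954654 to 89980983) stood at 30.8 ± 3.25 FPKM in Eed CTR and 24.8 ± 3.01 in matKO 4-cell libraries (log2 change -0.30, SE 0.16, adjusted p = 0.667), and a gene-level FPKM does not show whether an exon is deleted. In the matKO libraries Ezh2 stood at 85.4 ± 3.35 FPKM against 80.8 ± 3.68, and Suz12 at 226 ± 55.6 against 196 ± 58.1, with adjusted p = 0.887 and 0.863.

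PR-DUB OE was compared with CTR first at the 2-cell stage; H2AK119ub itself is not measured in these tables. Genes with little RNA in controls were found at several FPKM in OE embryos. Dio3 (chromosome 12, 110279068 to 110281097), an imprinted gene encoding the thyroid hormone inactivating deiodinase, rose from 0.62 ± 0.728 to 9.71 ± 1.65 FPKM. Socs2 (chromosome 10, 95385362 to 95417180), a suppressor of cytokine signalling, rose 12.1-fold to 9.72 ± 1.41 FPKM (log2 change 2.57, SE 0.21, adjusted p = 0.000211). Irf2bpl rose 7.81-fold to 12.4 ± 2.18 FPKM, and the pluripotency factor Klf4 rose 2.1-fold from 34.4 ± 2.96 to 72.1 ± 5.4 FPKM. Of 15055 genes tested, 177 were called, 148 higher and 29 lower (82 and 51 after rescaling). A control mean under 1 FPKM was found for 60 of the 148 higher ones and for 4070 of all genes tested. Other large rises were those of Trp53bp2 (9.23-fold), Zfp800 (10.5-fold), Zc3h7a (5.43-fold), Atp1b2 (6.03-fold), Phlda2 (8.04-fold), Zfp428 (5.75-fold) and the growth factor gene Pdgfa (5.4-fold). The falls were smaller. Cwc25, a splicing factor, fell from 38 ± 2.62 to 16.4 ± 0.598 FPKM. The histone chaperone gene Anp32e fell from 116 ± 0.0545 to 59 ± 2.91, Sbds, which acts in ribosome assembly, from 36.8 ± 2.53 to 18.6 ± 4.28, and Ptpn2 from 210 ± 9.31 to 121 ± 5.54. Efcab12, Ankrd35, Rpl36a-ps2, Prcc, Nol7 and Rpl35 fell by 1.06, 0.80, 0.76, 0.74, 0.74 and 0.70 on the log2 scale.

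Of 74 developmental regulators tested at the 2-cell stage, 6 rose and 0 fell by limma (11 rose and 0 fell adjusted over the list alone; 3 and 0 after rescaling). Irx2 rose from 1.39 ± 0.783 to 6.47 ± 0.49 FPKM, Tbx1 from 0.244 ± 0.288 to 2.78 ± 0.485 and Gata2 from 1.34 ± 0.986 to 6.31 ± 1.17. Their median log2 change was 0.37 (0.126 with no filter and 0.794 with a pseudocount of 0.1), the list was higher than other genes (camera adjusted p = 4.23e-06), and adjusted p = 0.182 with an estimated correlation. With fry of limma, which asks whether a list moves in 1 direction rather than against other genes, the list had an adjusted p of 0.0013. Of 23 canonical imprinted genes, 3 rose and 0 fell (3 adjusted over the list alone): Cdkn1c, a cell cycle inhibitor, to 34.7 ± 7.13 FPKM from 14.1 ± 5.01, Phlda2 to 7 ± 3.22 from 0.87 ± 0.464, and Plagl1 to 4.37 ± 0.114 from 1.08 ± 0.748. After rescaling 0 of them were called, and the list had camera adjusted p = 0.107. None of 13 H3K27me3-imprinted genes was called by limma (0 also adjusted over the list alone; camera adjusted p = 0.107). Sox2 rose with Klf4 among 24 pluripotency genes (2 rose, and 2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.863). The PRC2 list had 1 call of 14 (1 over the list alone; median -0.008, mean 0.108, camera adjusted p = 0.985). This was E130012A19Rik, which rose from 1.08 ± 0.0584 to 5.76 ± 0.436 FPKM. Ribosomal protein genes were lower as a group (median log2 change -0.28, 74 of 88 negative, camera adjusted p = 3.59e-17; adjusted p = 0.428 with an estimated correlation). Rpl35 was the 1 called (1 adjusted over the list alone), and fry gave an adjusted p = 0.147. Ribosome biogenesis genes, 0 of 58 called by limma, were lower likewise (median -0.18, -0.27 after rescaling; camera adjusted p = 2.22e-07; adjusted p = 0.558 with an estimated correlation). So was the spliceosome, where Snrpc fell (1 of 45; 2 lower adjusted over the list alone and 2 after rescaling; median -0.06, -0.141 after rescaling; camera adjusted p = 0.022; adjusted p = 0.558 with an estimated correlation). Genes that are higher in late 2-cell embryos than in oocytes were lower than other genes (25 rose and 9 fell of 1777, 41 and 24 adjusted over the list alone, 16 and 20 after rescaling; camera adjusted p = 0.000221, and adjusted p = 0.558 with an estimated correlation). Socs2, Irf2bpl, Foxi3 and Kpna4 were among the rises. Also called were Zfp36l2 (4.31-fold higher) among the maternal transcripts, D5Ertd577e (3.52-fold lower) among the 2-cell-stage transient genes, and Jade3, Maged1 (higher) and Vcp-rs (lower) on the X chromosome, where Xist stood at 0.0466 to 0.122 FPKM.

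The 2-cell PR-DUB count rests on every library: 12 genes were called without CTR replicate 1, 13 without CTR replicate 2, 7 without OE replicate 1 and 20 without OE replicate 2, against 2130 at an unadjusted p under 0.05 in the full limma fit (753 would be found with no change). A fit on these 4 libraries alone called 4 genes. Of the 41 called genes that the naming rule picked, Socs2, Irf2bpl, Foxi3 and Kpna4 kept their calls whichever library was left out, and rescaling ended calls that include those of Zfp800, Zc3h7a, Phlda2, Cdkn1c, Plagl1 and Sox2. A pseudocount of 0.1 ended the calls of Atp1b2, Phlda2, Efcab12, Ankrd35, Irx2, Gata2, Cdkn1c, Plagl1 and Sox2.

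More genes were called between PR-DUB OE and CTR at the 4-cell stage. Cd24a (chromosome 10, 43578284 to 43584265), a surface glycoprotein gene, rose 12.7-fold from 2.97 ± 0.0138 to 37.8 ± 8.47 FPKM (log2 change 3.27, SE 0.33, adjusted p = 0.000444). The imprinted gene Gnas (chromosome 2, 174284320 to 174346744) rose 7.09-fold to 31.2 ± 0.624 FPKM, and Ldha, for lactate dehydrogenase, rose from 0.324 ± 0.117 to 7.99 ± 3.36 FPKM. Ddit3 (chromosome 10, 127290774 to 127296288), the CHOP factor of the integrated stress response, fell 12.6-fold from 29.1 ± 1.21 to 2.31 ± 0.601 FPKM (adjusted p = 0.000444), and the homeobox gene En2 fell 6.23-fold from 14 ± 0.512 to 2.25 ± 1.03 FPKM. Of 15055 genes, 2368 were called, 1855 higher and 513 lower. A control mean under 1 FPKM was found for 533 of the 1855 higher ones and for 4174 of all 15055 genes tested, a like share. Rescaling the libraries shifted the median log2 change of all genes from 0.13 to -0.03 and gave 2301 calls, 1064 higher and 1237 lower, of which 1577 were also called without rescaling. The direction of the excess therefore changed with the scaling, and rescaled counts are given with the groups below.

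Other large rises at the 4-cell stage were those of Plac9b (to 7.01 ± 1.63 FPKM), Isca2 (to 5.81 ± 1.06), Rexo2 (7.01-fold), Nxf2 (5.97-fold), Abracl (9.17-fold) and the small heat shock gene Hspb1 (13-fold). Xlr, X-linked, was listed at 0 in both controls and at 8.92 and 5.06 FPKM in OE. Large falls were those of Grcc10 (11.4-fold), the mucin gene Muc3 (11.9-fold), Cyp1a2 (62.8-fold, from 7.69 ± 6.08 FPKM), n-R5s88 (11.8-fold), Esp24 (5.61-fold), Ier5 (7.62-fold) and Tmsb15a (6.48-fold). Rnu3b2, a U3 small nucleolar RNA, stood at 53.5 and 14 FPKM in controls and was listed at 0 in both OE libraries, as was Gtpbp4-ps3 after 7.36 and 5.8 FPKM.

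Developmental regulators, primitive endoderm genes and the imprinted lists were higher than other genes by camera with the preset correlation, and with an estimated correlation none of these calls was kept. Of 74 developmental regulators 24 rose and 1 fell (28 and 1 adjusted over the list alone; 21 and 2 after rescaling). Six2 rose from 0.315 ± 0.274 to 2.91 ± 0.369 FPKM, Msx1 from 1 ± 0.000839 to 5.45 ± 1.83 and Hoxa13 from 0.119 ± 0.052 to 1.76 ± 0.112, while En2 fell. The list's median log2 change was 0.54, 0.206 with no filter and 0.888 with a pseudocount of 0.1 (camera adjusted p = 0.00143, adjusted p = 0.262 with an estimated correlation, fry adjusted p = 0.000119). Fry, which makes no comparison with other genes, also gave low values for lists without a camera call. Examples are p53 targets (fry adjusted p = 0.000386) and heat shock genes (fry adjusted p = 0.00194). Of 7 primitive endoderm genes 4 rose and 0 fell (4 adjusted over the list alone; 2 after rescaling). Pdgfra, a receptor of that lineage, rose from 0.488 ± 0.0992 to 4.66 ± 0.0351 FPKM, Gata6 from 9.67 ± 1.97 to 20.6 ± 0.277, and Lamc1 and Lamb1 2.07-fold and 1.53-fold (camera adjusted p = 0.0052; adjusted p = 0.253 with an estimated correlation). Of 13 H3K27me3-imprinted genes 4 rose and 0 fell (6 adjusted over the list alone; 2 after rescaling). Rbms1 rose to 2.84 ± 1.11 FPKM, Slc38a4 to 1.34 ± 0.0916, and Enc1 to 10.2 ± 1.73. Xist (chromosome X, 103460366 to 103483254), which silences the X chromosome, rose from 3.6 ± 0.562 to 20.3 ± 14.1 FPKM (adjusted p = 0.0499). For Xist, a difference in the sex of the pools cannot be told apart from an effect of PR-DUB. The Xist and Enc1 calls ended with rescaling, and all 4 calls with a pseudocount of 0.1. The list had camera adjusted p = 0.0264, 0.0883 with that pseudocount, and adjusted p = 0.467 with an estimated correlation. Gab1, Sfmbt2 and Jade1 were 1.43-fold, 6.68-fold and 1.92-fold higher without a call (adjusted p = 0.517, 0.0816 and 0.164). Of 23 canonical imprinted genes 6 rose and 0 fell (9 adjusted over the list alone; 5 after rescaling), among them Gnas, Inpp5f (2.71-fold), Kcnq1ot1 (3.09-fold) and Ndn (to 1.49 ± 0.649 FPKM), with camera adjusted p = 0.0264 and adjusted p = 0.253 with an estimated correlation. Of 31 PR-DUB and PRC1 subunits 8 rose and 1 fell (12 and 2 adjusted over the list alone; 5 and 4 after rescaling; camera adjusted p = 0.0741), with Cbx6 (12.2-fold), Ogt (2.37-fold), Yaf2 (3.7-fold) and Rnf2 (1.72-fold) higher and Asxl2 lower. Of 14 PRC2 genes and demethylases Rbbp4 rose 1.96-fold and Phf1 fell 1.58-fold (the same counts over the list alone; 1 and 2 after rescaling; camera adjusted p = 0.738), and the list's median, 0.21, turned to -0.03 with rescaling.

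None of the lists in this paragraph passed camera at the 4-cell stage. All but glycolysis had calls in both directions. Of 45 spliceosome genes 10 rose and 1 fell (12 and 3 adjusted over the list alone; 7 rose and 8 fell after rescaling; camera adjusted p = 0.354). Snrnp200 and Sf3a1 rose 2.26-fold and 2.2-fold and Lsm7 5.43-fold, and Sf3b1 fell from 298 ± 6.16 to 176 ± 8.24 FPKM. Of 32 proteasome genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; 2 and 1 after rescaling; camera adjusted p = 0.105). Psmc6 (2.23-fold), Psma1 (2.03-fold), Psmc3 (2.27-fold) and Psmb3 (2.2-fold) rose. Of 18 glycolysis genes 4 rose and 0 fell (7 and 1 adjusted over the list alone; 3 and 1 after rescaling; camera adjusted p = 0.0741). The rises were those of Ldha, Pkm (2.13-fold), Pgk1 (2.43-fold) and Aldoa (1.78-fold). Of 26 p53 targets 8 rose and 3 fell (11 and 4 adjusted over the list alone; 6 and 5 after rescaling; camera adjusted p = 0.357). Phlda3 (6.6-fold), Xpc (3.59-fold) and Polk (5.46-fold) rose and Plk2 (2.3-fold) fell. Of 27 stress response genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; 5 and 5 after rescaling; camera adjusted p = 0.805). Sdf2l1 (6.42-fold), Hsp90b1 (2.19-fold) and Shmt2 (5.87-fold) rose and Ddit3 fell. The median, 0.04 with a mean of 0.15 and a test in the lower direction, turned to -0.19 with rescaling. Of 14 heat shock genes 6 rose and 3 fell (9 and 3 adjusted over the list alone; 4 and 3 after rescaling; camera adjusted p = 0.192). Chordc1 (2.4-fold), Hspb1 and Bag3 (2.38-fold) rose and Hspa1b (2.46-fold) fell. Of 24 pluripotency genes 4 rose and 1 fell (7 and 1 adjusted over the list alone; 1 and 4 after rescaling; camera adjusted p = 0.696). Prdm14 rose to 3.08 ± 0.756 FPKM, Zfp42 2.08-fold and Tbx3 2.45-fold, and Klf17 fell from 259 ± 12.3 to 151 ± 21.7. Of 14 trophectoderm genes Hand1 (2.18-fold) and Tfap2a (5.87-fold) rose and Id2 (3.02-fold) fell (2 and 1 also adjusted over the list alone; 1 and 1 after rescaling; camera adjusted p = 0.568).

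By camera with the preset correlation the maternal, transient 2-cell, ribosomal protein and ribosome biogenesis lists were lower than other genes, and with an estimated correlation none of these calls was kept. In that order, fry gave these lists adjusted p = 0.125, 0.525, 0.498 and 0.631. Of 76 maternal transcripts 2 rose and 6 fell (0 and 4 adjusted over the list alone; 0 and 11 after rescaling). Ccnb1 (1.43-fold), Magoh (1.33-fold), Ccnb3 (2.2-fold) and Fbxw15 (2.37-fold) fell. Camera gave an adjusted p = 0.00115, and adjusted p = 0.281 with an estimated correlation. Among 55 transient genes of the 2-cell stage Plk2 and Tcstv1 fell (0 rose; 1 fell adjusted over the list alone; 7 after rescaling), to 14.5 ± 3.11 and 21 ± 15.8 FPKM (camera adjusted p = 0.00143; adjusted p = 0.467 with an estimated correlation). No ribosomal protein gene of 88 was called by limma, also over the list alone, and 21 fell after rescaling (median log2 change -0.12, -0.396 after rescaling; camera adjusted p = 0.000545; adjusted p = 0.556 with an estimated correlation). In ribosome biogenesis 4 rose and 4 fell of 58 (5 and 6 adjusted over the list alone; 2 and 15 after rescaling; camera adjusted p = 0.0052, adjusted p = 0.596 with an estimated correlation). Mphosph10 (1.57-fold), Rrp1b (1.94-fold), Npm1 (1.44-fold) and Dkc1 (1.58-fold) rose, and the calls of Npm1 and Dkc1 ended with rescaling. Of 1777 genes higher in late 2-cell embryos than in oocytes 112 rose and 122 fell (101 and 113 adjusted over the list alone; 41 and 299 after rescaling). Camera placed that list below other genes (adjusted p = 0.00143; adjusted p = 0.467 with an estimated correlation), with a median of -0.02 and a mean of 0.003. Of the 1550 lower in late 2-cell embryos 263 rose and 26 fell (279 and 29 adjusted over the list alone; 152 and 45 after rescaling; camera adjusted p = 0.0957). Ehd4 (3.31-fold), Commd3 (4.86-fold), Mael (4.28-fold) and Hbs1l (3.48-fold) were among the rises. None of the 15 mitochondrially encoded genes was called by limma (camera adjusted p = 0.0601; 10 fell after rescaling). Of 599 X-linked genes 104 rose and 25 fell (116 and 30 adjusted over the list alone; 68 and 37 after rescaling; camera adjusted p = 0.276). Phf6 (4.85-fold) and Tbl1x (18.6-fold) were among the rises. Of 11 Y-linked genes Kdm5d fell 2.87-fold (0 adjusted over the list alone; 0 rose and 2 fell after rescaling; median 0.09, mean -0.10, and median -0.10 with rescaling). Per library, the mean log2(FPKM + 1) of X-linked genes was 2.134 and 2.155 in CTR and 2.442 and 2.377 in OE. That of Y-linked genes was 1.633 and 1.754 in CTR and 1.598 and 1.589 in OE. For genes of these chromosomes a difference in the sex of the pools cannot be told apart from an effect.

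No single library carried the 4-cell PR-DUB calls, although their number fell to 1029 without CTR replicate 1, 1044 without CTR replicate 2, 1007 without OE replicate 1 and 1254 without OE replicate 2. A fit on these 4 libraries alone called 1653 genes. Of the 90 called genes that the naming rule picked, 38 lost their call when some library was left out and 12 with rescaling (Xist, Enc1, Npm1, Dkc1, Psma1, Psmb3, Zfp42, Tbx3, Hand1, Lamc1, Lamb1 and Aldoa). A pseudocount of 0.1 ended 14 (Abracl, Xist, Slc38a4, Rbms1, Enc1, Kcnq1ot1, Ndn, Psmb3, Prdm14, Hand1, Id2, Gata6, Areg and Kdm5d).

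**Figure D1:**
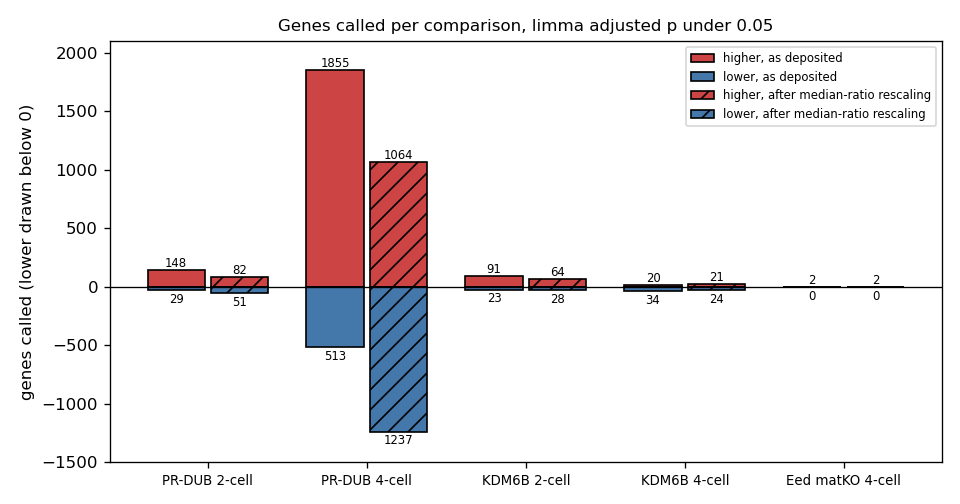
Number of genes called by limma at an adjusted p under 0.05 in each comparison of treated with control libraries (higher above 0, lower below 0), with FPKM as deposited (plain bars) and after rescaling (hatched bars). PR-DUB 4-cell has 1855 higher and 513 lower calls as deposited and 1064 higher and 1237 lower after rescaling.

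The PR-DUB effect differed between the stages. The difference of the 4-cell and 2-cell effects was called for 262 genes by limma, 155 with a more positive effect at the 4-cell stage and 107 with a more negative one (94 and 175 after rescaling). It was called for 20 to 126 genes with 1 library left out: 20 without OE 2-cell replicate 1 and 126 without OE 4-cell replicate 2. Primitive endoderm genes had the more positive effect at the 4-cell stage (1 of 7 called, 4 over the list alone; camera adjusted p = 0.0187, adjusted p = 0.258 with an estimated correlation). So had the spliceosome (2 of 45 called, 10 over the list alone; camera adjusted p = 0.0318) and the proteasome (0 called by limma; camera adjusted p = 0.0335), while mitochondrially encoded genes had the more negative one (14 of 15 negative, 0 called by limma; camera adjusted p = 0.0187). For these 3 lists the adjusted p = 0.708 with an estimated correlation. The calls of the 2 stages overlapped: 47 genes rose at both against 18.2 for independent lists (Fisher's exact test across genes, p = 3.58e-10), Jade3, Mael and Maged1 among them. Ankrd35, Gm29609, Taf1d, Vcp-rs and Zfp217 fell at both, 5 genes against 0.988 (Fisher's exact test, p = 0.00272). Both comparisons share 1 estimate of spread per gene and genes are not independent, so these p-values can be too small. After rescaling the stages shared 24 higher and 20 lower calls. Gm29609 and Zfp217 are named as members of the lower overlap, chosen after their values were seen. Of the 177 genes called at the 2-cell stage 76.8% had the same sign at the 4-cell stage. The median log2 changes of all genes, 0.081 and 0.129 at these stages, were above 0, which raises that share by itself. Across all genes, which are not independent replicates, the effects correlated at r = 0.178.

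**Figure D2:**
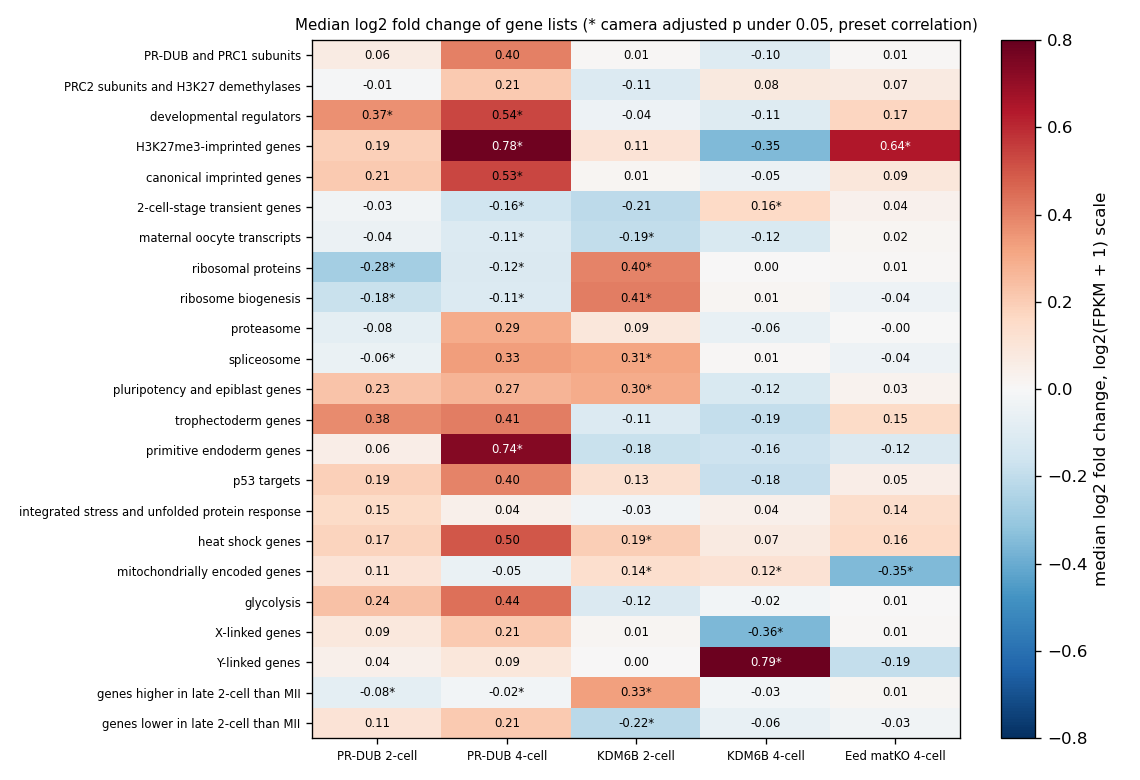
Median log2 change of each gene list (lines) in each comparison of treated with control libraries (columns), as colour and number; a star marks a camera adjusted p under 0.05 with the preset correlation. Developmental regulators have medians of 0.37 and 0.54 in PR-DUB OE at the 2-cell and 4-cell stage, and the PRC2, stress response and Y-linked medians of PR-DUB 4-cell change sign after rescaling.

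KDM6B OE was compared with CTR first at the 2-cell stage; H3K27me3 itself is not measured in these tables. Klrg2 (chromosome 6, 38625693 to 38637242) rose 5.96-fold from 3.33 ± 0.819 to 19.9 ± 0.0313 FPKM (log2 change 2.28, SE 0.29, adjusted p = 0.00717). Bzw2 rose 3.39-fold to 42.7 ± 11 FPKM (adjusted p = 0.00403), the epithelial adhesion gene Epcam 3.18-fold to 40.1 ± 10.1, Scd1, for a fatty acid desaturase, 3.49-fold to 14.7 ± 2.27, and the growth factor gene Fgf4 from 1.59 ± 0.17 to 6.36 ± 2.25 FPKM. Lsm14b (chromosome 2, 180024987 to 180035465), an RNA-binding protein gene, fell 2.67-fold from 408 ± 8.35 to 153 ± 30.3 FPKM (adjusted p = 0.00488), and Gdf9, an oocyte growth factor gene, fell from 132 ± 22.1 to 72.4 ± 7.02 FPKM. Of 15055 genes 114 were called, 91 higher and 23 lower (64 and 28 after rescaling). Tbc1d9 (5.41-fold), Mid1ip1 (3.88-fold), Acot8 (3.68-fold), Sp6 (2.93-fold) and Sox13 (3.26-fold) rose. Cpxm2 (3.66-fold), Tbc1d8 (2.79-fold), Pdpn (2.52-fold), Lamp1 (2.3-fold), Slc26a9 (2.4-fold), Olfr976 (2.52-fold), Ndufb10 (2.3-fold), Dcbld2 (2.01-fold) and Cds1 (2.05-fold) fell.

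The calls followed the change between oocyte and embryo. Of 1777 genes higher in late 2-cell embryos than in oocytes 57 rose and 0 fell (292 and 6 adjusted over the list alone; camera adjusted p = 4.27e-21, adjusted p = 0.0839 with an estimated correlation), and of the 1550 lower ones 0 rose and 12 fell (0 and 12 adjusted over the list alone; camera adjusted p = 1.94e-12). The second call was kept with an estimated correlation (adjusted p = 0.0186). Of 88 ribosomal protein genes 9 rose and 0 fell (33 and 0 adjusted over the list alone; 4 after rescaling). Rpl12 (1.83-fold), Rps14 (1.69-fold), Rplp1 (1.59-fold) and Rpl13 (2.14-fold) rose, and the list's median log2 change was 0.40 (camera adjusted p = 4.27e-21; adjusted p = 0.151 with an estimated correlation; fry adjusted p = 0.0215). Ribosome biogenesis genes had 0 calls of 58 by limma and 24 higher adjusted over the list alone (median 0.41, camera adjusted p = 2.03e-16; adjusted p = 0.151 with an estimated correlation). In the spliceosome list 1 of 45 was called, Snrpb, 2.6-fold higher (3 over the list alone; camera adjusted p = 2.89e-07, adjusted p = 0.145 with an estimated correlation). Of 24 pluripotency genes Fgf4 and Dppa5a rose (4 over the list alone; camera adjusted p = 0.00403, adjusted p = 0.145 with an estimated correlation). The maternal list, with Gdf9 lower and Ccnb1 and Dppa3 1.51-fold and 1.49-fold higher (3 rose and 2 fell adjusted over the list alone), was lower as a group (median -0.19, camera adjusted p = 0.000235; adjusted p = 0.158 with an estimated correlation). The calls of Ccnb1, Dppa3 and the transient 2-cell gene Trim43a ended with rescaling. Heat shock genes had 0 limma calls of 14 (2 higher over the list alone; camera adjusted p = 0.037, adjusted p = 0.158 with an estimated correlation). All 15 mitochondrially encoded genes were positive with 0 limma calls (0 over the list alone; camera adjusted p = 0.00123, adjusted p = 0.421 with an estimated correlation). Neither list kept its camera call after rescaling (adjusted p = 0.13 each). Among 13 H3K27me3-imprinted genes Etv6 rose 2.99-fold (1 over the list alone; camera adjusted p = 0.205), with Gab1, Jade1 and Sfmbt2 not called (adjusted p = 0.681, 0.231 and 0.794), and among 74 developmental regulators Fgf4 rose (1 over the list alone; camera adjusted p = 0.177).

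The KDM6B 2-cell effect correlated across genes with the 4-cell minus 2-cell difference of the PR-DUB controls at r = 0.135 (rho = 0.157; genes are not independent replicates). It was 0.062 without OE replicate 2 and 0.164 without OE replicate 1. The values were -0.034, 0.014 and 0.021 for PR-DUB 2-cell, PR-DUB 4-cell and KDM6B 4-cell with the other experiment's controls. Of the 91 higher calls of KDM6B 2-cell 59.3% were genes higher at the control 4-cell stage, against 26.5% of all genes tested, and of the 23 lower calls 73.9% were lower there, against 30.2%. The count depended on single libraries: 37 genes were called without CTR replicate 1, 6 without CTR replicate 2, 353 without OE replicate 1 and 9 without OE replicate 2, and 1 in a fit on these 4 libraries alone. Of the 32 called genes that the naming rule picked, Bzw2, Lsm14b and C130074G19Rik (5.37-fold higher) kept their calls whichever library was left out. With a pseudocount of 0.1 those of Mid1ip1, Cpxm2, Slc26a9 and Olfr976 ended, and with no filter 16 of the 32.

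At the 4-cell stage KDM6B OE embryos had less RNA from X-linked genes and more from Y-linked genes. Of 599 X-linked genes 1 rose and 21 fell (3 and 110 adjusted over the list alone; 1 and 14 after rescaling), with a median log2 change of -0.36, -0.026 with no filter and -0.535 with a pseudocount of 0.1 (camera adjusted p = 3.74e-13; adjusted p = 0.105 with an estimated correlation). Uba1 (chromosome X, 20658326 to 20683179), a ubiquitin-activating enzyme gene, fell 2.46-fold from 98.5 ± 12.2 to 40.1 ± 3 FPKM (log2 change -1.27, SE 0.13, adjusted p = 0.00235), Jade3 4.23-fold, Mbnl3 11.4-fold and Hcfc1, a PR-DUB cofactor, 2.09-fold. Rhox9 (chromosome X, 37899097 to 37901770), a homeobox gene, rose from 0.034 ± 0.048 to 11.5 ± 1.12 FPKM (adjusted p = 0.00017). None of 11 Y-linked genes was called over all genes by limma, 6 were higher adjusted over the list alone, and their median was 0.79 (0.74 after rescaling, 0.03 with no filter and 2.791 with a pseudocount of 0.1; camera adjusted p = 1.96e-06, adjusted p = 0.28 with an estimated correlation). Per library, Eif2s3y stood at 3.94 and 0 FPKM in CTR and 10.4 and 17.3 in OE, Ddx3y at 0.681 and 0 against 2.03 and 4.03, Uty at 0.787 and 0 against 2.81 and 4.6, and Usp9y at 0.825 and 0 against 2.15 and 3.6. Kdm5d stood at 2.03 and 0.162 against 1.38 and 1.81. Xist varied within both groups, at 3.36 and 13 FPKM in CTR and 25.7 and 5.87 in OE (adjusted p = 0.691).

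**Figure D3:**
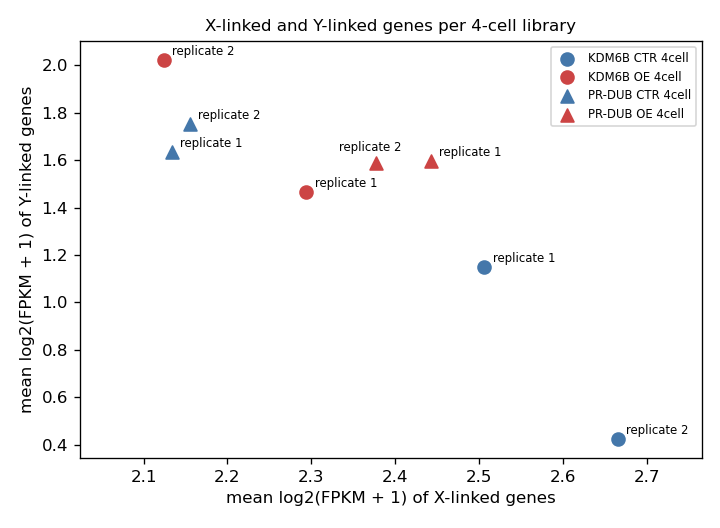
Mean log2(FPKM + 1) of X-linked (horizontal axis) and Y-linked genes (vertical axis) tested, 1 point per 4-cell library of the KDM6B and PR-DUB experiments. KDM6B OE libraries sit at X means of 2.294 and 2.124 and Y means of 1.466 and 2.022, and their controls at X means of 2.506 and 2.665 and Y means of 1.149 and 0.423.

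Outside the sex chromosomes 32 autosomal genes were called. Of 15055 genes 54 were called in all, 20 higher and 34 lower. The mitochondrial ADP/ATP carrier gene Slc25a4 rose 4.31-fold to 30.5 ± 7.12 FPKM, Calm2, a calmodulin gene, 2.42-fold to 146 ± 4.65, Qrich1 2.69-fold to 20.6 ± 0.766, Zranb2 2.4-fold, Mrps6 2.01-fold, the transcription factor gene Sp1 2.11-fold, Olfr376 6.82-fold, Dnal1 5.89-fold and the heat shock gene Dnajb1 2.04-fold. Snord82 was listed at 0 in both controls and at 2.07 and 7.96 FPKM in OE. Slc5a11 (8.3-fold), Akr1c21 (4.59-fold), Fbxo33 (2.69-fold), the homeobox gene Dlx5 (4.63-fold) and the metallothionein gene Mt1 (1.92-fold, from 544 ± 89.7 FPKM) fell. So did the X-linked Nxf2 (10.7-fold), Gpc4 (20.4-fold), Magea5 (7.42-fold), Atp6ap1 (2.95-fold), Dmd (3.55-fold) and Slc6a8 (2.85-fold). None of 13 H3K27me3-imprinted genes was called by limma (0 over the list alone; camera adjusted p = 0.546), nor was Kdm6a, the X-linked paralog of Kdm6b, at 20.4 ± 1.9 FPKM in OE and 32.7 ± 3.65 in CTR (adjusted p = 0.0811). All 15 mitochondrially encoded genes were positive (0 limma calls, 1 over the list alone; camera adjusted p = 0.000234, adjusted p = 0.541 with an estimated correlation). The transient 2-cell list, with 0 limma calls of 55 (1 higher over the list alone), had camera adjusted p = 0.0403, 0.0648 after rescaling and adjusted p = 0.834 with an estimated correlation. The count was 15 without CTR replicate 2, 33 without OE replicate 2, 91 without OE replicate 1 and 1 in a fit on these 4 libraries alone, against 1746 genes at an unadjusted p under 0.05 (753 would be found with no change). Rhox9, Qrich1, Calm2, Uba1 and Gm4675 (8.35-fold higher) kept their calls whichever library was left out. Rescaling ended those of Sp1, Nxf2, Atp6ap1, Dmd, Slc6a8, Dkc1 and Tmem169, and a pseudocount of 0.1 ended 19 of the 31 calls that the naming rule picked.

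The KDM6B effects of the 2 stages differed for 21 genes by limma, 6 more positive and 15 more negative at the 4-cell stage (1 without CTR 2-cell replicate 2 and 65 without OE 4-cell replicate 1; 5 and 6 after rescaling; 2 on these libraries alone). Ribosomal protein, ribosome biogenesis and X-linked genes had the more negative effect at the 4-cell stage (camera adjusted p = 4.21e-11, 1.9e-08 and 4.11e-07; adjusted p = 0.356 with an estimated correlation for each). The spliceosome and pluripotency lists went the same way (camera adjusted p = 0.00118 and 0.0496; adjusted p = 0.356 with an estimated correlation for each). Y-linked and transient 2-cell genes had the more positive effect (camera adjusted p = 0.00309 and 0.042; adjusted p = 0.356 and 0.733 with an estimated correlation). The PR-DUB and KDM6B effects differed from each other for 259 genes at the 2-cell stage, 87 more positive and 172 more negative with PR-DUB (2 without PR-DUB OE replicate 1 and 517 without KDM6B OE replicate 1; 9 on these libraries alone). There 20 of 88 ribosomal protein genes were more negative with PR-DUB (52 over the list alone; camera adjusted p = 3.28e-29, adjusted p = 0.147 with an estimated correlation), and 2 of 74 developmental regulators more positive (6 more positive and 1 more negative over the list alone; camera adjusted p = 4.73e-05, adjusted p = 0.147 with an estimated correlation). At the 4-cell stage the effects differed for 1395 genes, 1090 more positive and 305 more negative with PR-DUB (544 and 704 after rescaling, which moved the median of all genes from 0.19 to -0.02; 579 in all without PR-DUB CTR replicate 2; 125 on these libraries alone). There 19 developmental regulators were more positive and 1 more negative (22 and 2 over the list alone; camera adjusted p = 0.00068, adjusted p = 0.281 with an estimated correlation), and 127 X-linked genes were more positive and 9 more negative (178 and 15 over the list alone; camera adjusted p = 3.02e-05, adjusted p = 0.281 with an estimated correlation). Calls of PR-DUB and KDM6B were shared in 3 and 0 genes (higher and lower) at the 2-cell stage and in 4 and 1 at the 4-cell stage. Calls in opposite directions numbered 2 at the 2-cell stage (Gm29609 and Rpl35, lower with PR-DUB). Of 4-cell calls 10 genes were higher with PR-DUB and lower with KDM6B, the X-linked Uba1, Jade3 and Phf6 among them, and 4 the reverse (Dnajb1, Gm4675, Mrps6 and Qrich1). Of the 34 lower KDM6B 4-cell calls 21 were X-linked. For X-linked and Y-linked genes a difference in the sex of the KDM6B or PR-DUB pools cannot be told apart from an effect. That limit holds for the X-linked and Y-linked lists of this paragraph too. At the 2-cell stage Bcl2l14, Gm13241 and Smtn rose with both (3 against 0.895 for independent lists, Fisher's exact test p = 0.0605) and no gene fell with both. At the 4-cell stage Ddah1, Hjurp, P4ha3 and RP23-214I6.5 rose (4 against 2.46, Fisher's exact test p = 0.299) and Gm595 fell with both (1 against 1.16, Fisher's exact test p = 1). These genes are named as the members of the overlaps, chosen after their values were seen. Across genes, which are not independent replicates, the effects correlated at r = -0.068 at the 2-cell and -0.098 at the 4-cell stage.

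Eed matKO was compared with CTR at the 4-cell stage. The genes known to be imprinted by H3K27me3 were higher as a group: 11 of 11 tested had a positive log2 change, with a median of 0.64, 0.377 with no filter (camera adjusted p = 1.66e-08; adjusted p = 0.753 with an estimated correlation). With fry the adjusted p was 0.214. Xist stood at 8.16 and 9.67 FPKM in CTR and 68.9 and 30.3 in matKO (log2 change 2.24, SE 0.37, adjusted p = 0.331). Jade1 stood at 12 ± 0.975 and 23.5 ± 6.67 FPKM, Gab1 at 9.42 ± 1.52 and 16.5 ± 2.93, Bbx at 18.7 and 20.3 against 38.2 and 38.3, Etv6 at 9.81 and 11.2 against 17.7 and 24.4, and Smoc1 at 2.19 ± 0.168 and 3.29 ± 0.9. Sfmbt2 stood at 1.71 ± 0.0853 and 2.67 ± 1.64 FPKM and overlapped between groups, and Slc38a4 stood at 0.469 to 0.519 FPKM. None of the 11 was called over all genes by limma, and 6 were higher adjusted over the list alone. The mitochondrially encoded genes went the other way, with 15 of 15 negative and a median of -0.35 (10 lower over the list alone, 0 over all genes by limma; camera adjusted p = 1.81e-10, adjusted p = 0.753 with an estimated correlation). mt-Cytb stood at 9460 and 8790 FPKM in CTR and 6580 and 6560 in matKO. No other list passed camera, developmental regulators (2 of 24 higher over the list alone, adjusted p = 0.163) and canonical imprinted genes (1 of 17, adjusted p = 0.163) included.

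**Figure D4:**
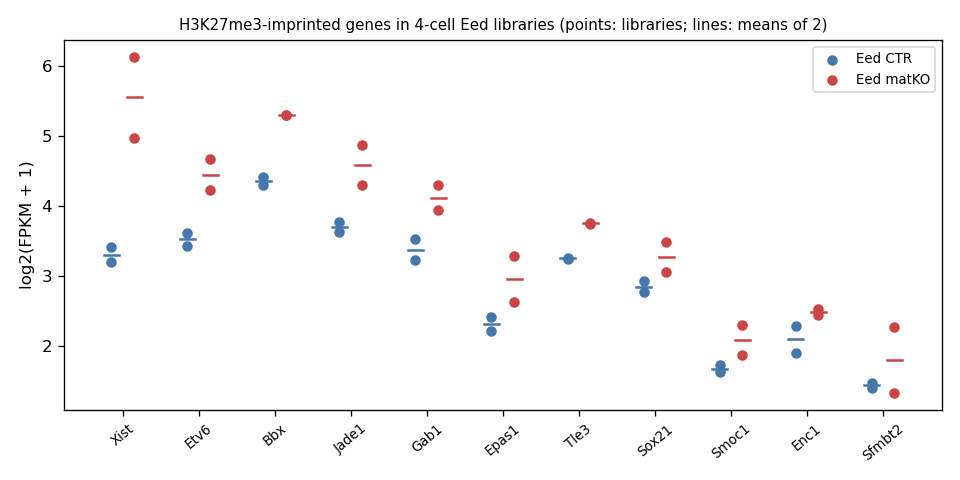
log2(FPKM + 1) of the 11 H3K27me3-imprinted genes tested in the Eed 4-cell libraries, 1 point per library (CTR blue, matKO red) and a line at each mean. All 11 genes have the higher mean in matKO, and Xist, at 68.9 and 30.3 FPKM against 8.16 and 9.67, has the largest difference.

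Over all 11679 genes limma called 2 in the Eed comparison, both higher, against 965 at an unadjusted p under 0.05 (584 would be found with no change). They are named here after their values were seen. Gm13230 (chromosome 4, 145446740 to 145450888), a pseudogene, was listed at 0 in both controls and at 41.9 and 32 FPKM in matKO (adjusted p = 0.0027), and Gm26079 (chromosome 5, 110692049 to 110692181), a small nucleolar RNA gene, rose from 6.06 and 5.23 to 86.3 and 99.6 FPKM (log2 change 3.82, SE 0.15, adjusted p = 0.0027). The largest uncalled differences were those of Mir8114, mmu-mir-3069, n-R5s93, Snora34, Tsga8 and Snord73a (adjusted p = 0.686, 0.668, 0.351, 0.732, 0.211 and 0.331), of which Tsga8 stood at 6.83 ± 0.944 FPKM in CTR and 0.531 ± 0.305 in matKO. The number called was 6 without CTR replicate 1, 3 without CTR replicate 2, 0 without matKO replicate 1 and 3 without matKO replicate 2. No call was shared with KDM6B 4-cell, and the effects correlated at r = 0.05 across genes, which are not independent replicates.

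Late 2-cell embryos against MII oocytes gives the normal change at genome activation. Of 13237 genes 10944 were called, 5034 higher and 5910 lower. Rescaling moved the median of all genes from -0.20 to 0.09 and gave 5708 higher and 5158 lower calls. With 1 library left out, a gene found only in the group left with 1 library cannot pass the filter. Between 11109 and 11557 genes were then tested instead of 13237. The median log2 change was -0.609 without late 2-cell replicate 1 and -0.607 without replicate 2. Without MII replicate 1 it was 0.104, and without MII replicate 2 it was 0.16. The filter alone moves these medians apart, so they cannot show whether the excess of lower genes rests on 1 library. Slc34a2 rose from 0.208 ± 0.000218 to 527 ± 32.3 FPKM (log2 change 8.77, SE 0.12, adjusted p = 6.2e-06), the metallothionein genes Mt1 and Mt2 to 364 ± 39.7 and 288 ± 11.2, and Btbd18, Rmrp, Hipk1, Prps1 and Alppl2 to 358, 349, 321, 239 and 331 FPKM. Scarna13 and Crxos were listed at 0 in both MII libraries and at 274 and 324 and at 249 and 196 FPKM in late 2-cell embryos. Rgs2 fell 73.8-fold, Obox2 47.3-fold, Glrx 60.8-fold, Oas1h 56.1-fold, Oas1c 49.2-fold, Fam162a 112-fold, Pabpn1l 73.4-fold, Gpr1 76.2-fold, Fetub 118-fold and Speer5-ps1 65.1-fold. Transient 2-cell genes rose (40 rose and 6 fell of 49, the same over the list alone; camera adjusted p = 1.16e-08, adjusted p = 0.467 with an estimated correlation), Obox6 and Ubtfl1 to 188 ± 4.96 and 114 ± 2.12 FPKM. Maternal transcripts fell (4 rose and 71 fell of 78, the same over the list alone; camera adjusted p = 3.84e-13, adjusted p = 0.41 with an estimated correlation), Plat 26-fold, Oog4 37.2-fold and Kpna7 27.6-fold. Ribosomal protein genes rose (77 rose and 4 fell of 86, the same over the list alone; camera adjusted p = 3.84e-13, adjusted p = 0.467 with an estimated correlation), with Rps19 at 166 ± 6.93 FPKM after 1.54 ± 0.448. Ribosome biogenesis (41 rose and 10 fell of 58; Nop2 to 97.7 ± 3.89 FPKM), mitochondrially encoded (13 and 0 of 15), p53 target (15 and 5 of 22; Sesn2 187-fold), pluripotency (12 and 5 of 19; Dppa4 18.4-fold) and H3K27me3-imprinted genes (7 and 0 of 8; Jade1 from 0.00976 ± 0.0138 to 18.5 ± 3.08 FPKM) were higher too, with the same counts over each list alone. Their camera adjusted p-values were 4.43e-05, 0.00218, 0.0167, 0.0167 and 0.0153, and adjusted p = 0.636, 0.834, 0.467, 0.467 and 0.636 with an estimated correlation.

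PR-DUB CTR 4-cell against 2-cell embryos gives the later normal change, used as a scale for the effects. Of 15055 genes 8532 were called, 3985 higher and 4547 lower. Rescaling moved the median of all genes from -0.04 to 0.07 and gave 4616 higher and 4045 lower calls. Bhmt rose 151-fold to 110 ± 7.88 FPKM, Tfeb 140-fold, Anpep 138-fold, Ckmt1 157-fold, Vnn1 to 50.3 ± 11.6 FPKM and Sox15 49.8-fold to 268 ± 28. U3, Prl3b1 and Hand1 were listed at 0 in both 2-cell controls and at 84.7 and 103, 77.4 and 88.3, and 53.3 and 47 FPKM at the 4-cell stage. Bmi1, a PRC1 subunit gene, fell 18-fold from 779 ± 1.54 to 43.2 ± 2.49 FPKM, Oog3 31.8-fold, Tesc 50.5-fold, Siah2 29-fold, Slain1 28-fold, Fam199x 26.6-fold, Oosp1 23.7-fold, Sebox 30.7-fold and Wee2, a meiotic kinase gene, 24.6-fold. Ribosomal protein genes rose (82 rose and 0 fell of 88, 82 and 1 over the list alone; camera adjusted p = 7.78e-31, adjusted p = 0.103 with an estimated correlation), as did the proteasome (29 and 1 of 32, the same over the list alone; 3.89e-11 and, with an estimated correlation, adjusted p = 0.103) and the spliceosome (29 and 2 of 45, the same over the list alone; 4.11e-07 and, with an estimated correlation, adjusted p = 0.103). Rpl7, Psma6 and Snrpb reached 555 ± 7.09, 138 ± 0.432 and 137 ± 16.3 FPKM. Maternal transcripts fell (6 rose and 56 fell of 76, the same over the list alone; camera adjusted p = 1.81e-10, adjusted p = 0.103 with an estimated correlation), with Btg4 16.9-fold and Omt2a 18.4-fold lower. Ribosome biogenesis (37 and 6 of 58; Ncl 3.63-fold), mitochondrially encoded (13 and 0 of 15, 14 and 0 over the list alone) and H3K27me3-imprinted genes (10 and 1 of 13; Bbx 10.6-fold) were higher, with camera adjusted p = 2.77e-06, 1.02e-05 and 0.0149 and adjusted p = 0.375, 0.321 and 0.375 with an estimated correlation. Snora74a, AC121821.1 and Hist2h2aa1 were called too but lost the call when some library was left out.

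Markers of cells that could travel with an embryo were low or followed the stage. Of 25 cumulus and granulosa markers Amhr2 and Areg were tested in the PR-DUB and KDM6B libraries, Amhr2 standing at up to 21.7 FPKM, and Areg fell with PR-DUB OE at the 4-cell stage (1.67 and 2.32 to 0 and 0.57 FPKM, adjusted p = 0.00674). Of 12 sperm and 11 blood markers 3 each were tested there (Ldhc, Prm2 and Tnp1; Cd52, Coro1a and Hba-a1), none was called with PR-DUB or KDM6B OE by limma, and the highest levels in those 4 comparisons were 3.38 FPKM (Tnp1) and 7.46 FPKM (Coro1a). None of the 1, 2 and 4 tested in the Eed libraries was called. Between late 2-cell embryos and oocytes Amhr2 and Cd52 rose and Cyp19a1 and Prm2 fell, and between control stages Areg, Coro1a and Hba-a1 rose and Amhr2 fell.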

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

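Of the tests below, those of an effect on X-linked genes alone, of the stage change behind the PR-DUB 4-cell calls, of scaling as the source of their number, and of OE pools being further along were chosen only after the result was seen, as was the demand that a test hold with each library left out.

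Effects that differed between stages or between manipulations, by a test of the difference itself, were called for 262 genes between the PR-DUB effects at the 4-cell and 2-cell stage and for 21 genes between the KDM6B effects at these stages. The PR-DUB and KDM6B effects differed for 259 genes at the 2-cell stage and for 1395 at the 4-cell stage. The counts with single libraries left out are given with the processing below.

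In KDM6B OE 4-cell libraries X-linked genes were lower (ratio to autosomal genes 0.683) and Y-linked genes higher (7.21). The Y-linked genes, part of the pattern itself, had a median log2 change of 0.785 with no gene called over all genes (fry adjusted p = 0.0857). With each library left out the median was 0.358 to 1.153, above the bound of 0.25 set for an effect of KDM6B on X-linked genes alone. The Y-linked rise was seen before that bound was set, so passing it restates the pattern and cannot decide on that explanation. Each group also has 2 libraries, and the controls lie far apart in mean Y-linked level, at 1.149 and 0.423. The OE libraries stood at 1.466 and 2.022, and the mean log2 change was 0.958. A candidate explanation is fewer female embryos in the OE pools: the 2 ratios solve to a male share of 9.73% in CTR and 70.1% in OE, and both OE libraries lie above both controls in mean Y-linked level. Without CTR replicate 1 the solution is 96% in CTR and 137% in OE, outside what a share can be, with 3 Y-linked genes left in the ratio and a Y ratio of 1.42. Without CTR replicate 2 it is 17.1% and 60.6%, without OE replicate 1 8.97% and 80.6%, and without OE replicate 2 10.3% and 55.9%. CTR replicates 1 and 2 also differ from each other, with X means of 2.506 and 2.665 and Y means of 1.149 and 0.423. OE cannot account for that, so the pools differ in X-linked and Y-linked RNA apart from OE. For the difference between OE and CTR, sex and an effect of KDM6B on either or both chromosomes cannot be told apart here. The sex of the embryos is not given in the sources used here.

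The 4-cell PR-DUB calls were many and mostly higher. Their direction changed with scaling, with 46.2% of the calls higher after rescaling against 78.3% before. Rescaling centres all genes (median 0.129 before, -0.027 after), which evens this split whether or not the excess comes from scaling, so scaling and a real excess cannot be told apart. As for the number of calls, 2301 genes were called after rescaling and 2368 before, and 1577 were called both ways. Those 1577 calls did not rest on the choice between the 2 scalings. The like totals cannot decide whether scaling is a source of calls, since rescaling ended some calls and made others. A shift of OE embryos along the normal stage change of all genes together is argued against by a correlation across genes of 0.014 with the KDM6B control stage difference (-0.01 to 0.036 with each library left out). That reference has limits: its controls carry high Kdm6b and its stages cross the sequencing split, and it correlated with the PR-DUB control difference at 0.722 across genes, which are not independent replicates. Single lists went both ways. Ribosomal protein genes, which rose between control stages, were lower in OE (camera adjusted p = 0.000545), as a lag would give. Maternal transcripts, which fell between control stages, were lower too (camera adjusted p = 0.00115), as a lag would not give. Neither call was kept with an estimated correlation, and a shift of part of the genes stays open. Low-level background reads cannot be told apart from an effect: of 11604 genes under 1 FPKM, 53.1% had the higher mean in OE, and 45.3% to 63.3% with each library left out. An effect of PR-DUB OE, which the design names, stays open.

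The KDM6B 2-cell effect ran along the normal stage change. Placing the libraries on the PR-DUB control stage difference restates this pattern and gives no separate evidence for OE pools being further along: both OE libraries lay above both controls on it, at 0.02 and 0.061 against 0.005 and -0.005, with a gap of 0.015 (0.013 to 0.056 with each library left out). An exact test of 2 against 2 cannot go below p = 0.333. Whether OE replicate 2 alone carries it cannot be told apart: without it the correlation was 0.062, and 0.042 to 0.068 with a further library left out, around the bound of 0.05 set before, and without OE replicate 1 it was 0.164. OE pools further along and an effect of KDM6B on the genes of the stage change cannot be told apart, since no measure of timing apart from these genes was used.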

How the results depend on the processing

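None of the alternatives below was chosen after the results were seen. Where a library is left out, the lone library of its group is assumed to vary like the other groups; where a value moved, the cause was not tested. Depth limits genes near 1 FPKM, which rest on 23.1 to 41.2 fragments at 2 kb. Of 278 values of named genes, 248 kept direction and side of the threshold with rescaling, 228 with a pseudocount of 0.1 and 234 with no filter. The replicate block was run for fewer of these values, since those of control 4-cell against 2-cell were left out. With it 145 did, 1 gained a call and 112 were no longer called. Calls ended for 40 of 41 in PR-DUB 2-cell, 10 of 90 in PR-DUB 4-cell, 32 of 32 in KDM6B 2-cell and 30 of 31 in KDM6B 4-cell. Of 29 gene list calls in the OE and Eed comparisons 26, 27 and 27 did, and with an estimated inter-gene correlation 1 did; list calls of the other comparisons were run under the estimated correlation alone. Calls ended for the H3K27me3-imprinted list of PR-DUB 4-cell (0.0883, pseudocount 0.1), genes higher in late 2-cell embryos in PR-DUB 4-cell (0.0531, no filter), heat shock genes of KDM6B 2-cell (0.0705, pseudocount 0.1; 0.13, rescaling), mitochondrially encoded genes of KDM6B 2-cell (0.13, rescaling) and transient 2-cell genes of KDM6B 4-cell (0.0593, no filter; 0.0648, rescaling). With single libraries left out 633 gene values stayed, 416 lost their call, 5 gained one and 16 changed sign. With the replicate block limma called 2 genes in PR-DUB 2-cell, 0 in KDM6B 2-cell, 2 in KDM6B 4-cell, 5 and 0 for the stage differences of the PR-DUB and KDM6B effects, and 1 and 528 for PR-DUB minus KDM6B at the 2-cell and 4-cell stage. Replicate numbers show no pairing: deviations of same-numbered libraries correlated across genes at -0.006 and 0.037 for PR-DUB 2-cell and 4-cell, -0.062 and -0.047 for KDM6B, 0.015 for Eed and 0.025 for late 2-cell against MII. The block was not run for control 4-cell against 2-cell, where the stages share no block. Fits on a comparison's own libraries called 4 (PR-DUB 2-cell), 1 (KDM6B 2-cell), 1 (KDM6B 4-cell), 2 (KDM6B stage difference), and 9 and 125 (PR-DUB minus KDM6B, 2-cell and 4-cell). A fold of at least 2 left 1286 genes in PR-DUB 4-cell and 55 in KDM6B 2-cell. A pseudocount of 0.1 gave 195 in KDM6B 2-cell, 24 in KDM6B 4-cell and 140 for the PR-DUB stage difference; PR-DUB and KDM6B shared 1 lower gene at the 2-cell stage (r = -0.035) and 2 higher and 0 lower at the 4-cell stage (r = -0.059), the PR-DUB stages shared 3 lower (r = 0.159), and correlations with the stage change were 0.03 for PR-DUB 2-cell and 0.086 for KDM6B 2-cell. No filter gave 106 in KDM6B 4-cell, 0 in Eed and 50 for the KDM6B stage difference, 1 shared lower gene at the 2-cell stage (r = -0.052) and 3 at the 4-cell stage, and stage correlations of -0.019 and 0.034 for PR-DUB 2-cell and 4-cell. Rescaling gave 11 for the KDM6B stage difference, 4 shared lower genes of PR-DUB and KDM6B at the 4-cell stage, 24 higher and 20 lower shared by the PR-DUB stages, and stage correlations of -0.013 and -0.021 for PR-DUB 2-cell and 4-cell. With 1 library left out the lowest and highest counts were 7 (without OE replicate 1) and 20 (OE replicate 2) in PR-DUB 2-cell, 1007 (OE replicate 1) and 1254 (OE replicate 2) in PR-DUB 4-cell, 6 (CTR replicate 2) and 353 (OE replicate 1) in KDM6B 2-cell, 15 (CTR replicate 2) and 91 (OE replicate 1) in KDM6B 4-cell, and 0 (matKO replicate 1) and 6 (CTR replicate 1) in Eed. For differences of effects they were 20 (PR-DUB OE 2-cell replicate 1) and 126 (PR-DUB OE 4-cell replicate 2) for PR-DUB stages, 1 (KDM6B CTR 2-cell replicate 2) and 65 (KDM6B OE 4-cell replicate 1) for KDM6B stages, 2 (PR-DUB OE 2-cell replicate 1) and 517 (KDM6B OE 2-cell replicate 1) for the manipulations at the 2-cell stage, and 579 (PR-DUB CTR 4-cell replicate 2) and 1531 (KDM6B CTR 4-cell replicate 1) at the 4-cell stage. Uncalled genes whose log2 change turned were Asxl1 (-0.08 to 0.04), Asxl3 (0 to 0.26) and Xist (-0.01 to 0.09) in PR-DUB 2-cell, Asxl3 (-0.15 to 0.05) in PR-DUB 4-cell, Gab1 (-0.6 to 0.38), Jade1 (-1.04 to 0.33) and Xist (-0.19 to 1.77) in KDM6B 4-cell, and Snora34 (-5.46 to 0.43), Sfmbt2 (-0.11 to 0.84) and Suz12 (-0.09 to 0.52) in Eed. Snora34 reached an adjusted p = 0.00905 without matKO replicate 2.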
